A study of Mus musculus with 4 samples.

How the data were processed

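Transcript levels were measured by RNA sequencing in 4 mammary tumour samples of 14-week-old female FVB mice carrying PyMT, 2 labelled Nr1d1+/+ and 2 labelled Nr1d1-/-. RNA was extracted with Trizol and libraries were built from 1.3 ug of total RNA with the Clontech SMARTer Stranded kit, per the labels' protocols. Reads were aligned with TopHat to the mouse assembly mm10, per the submitters' processing notes, and the deposited values are raw counts per gene symbol. Versions, the counting program, the gene annotation, whether counting used the strand, and whether ribosomal RNA was depleted are not given in the sources used here.

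All later steps were computed here from the deposited counts. The count files held 23238 gene symbols, of which 22862 were joined to GENCODE M21 (GRCm38, the same assembly as mm10), 22197 directly and 665 through a synonym, and 376 had no annotation. Symbols present more than once in a file were kept apart. Total counts were 19116279, 17768820, 15905404 and 18017279 in Nr1d1+/+ replicates 1 and 2 and Nr1d1-/- replicates 1 and 2, so that 1 count was 0.0523, 0.0563, 0.0629 and 0.0555 CPM and a floor of 3 counts was 0.157, 0.169, 0.189 and 0.167 CPM. These CPM values were taken over total counts without the TMM factors given below, so they are not on the exact scale of the reported levels. Floors and intervals of single samples cover counting error only. Genes with too few counts were left out with edgeR's filterByExpr (minimum count 10), which left 14801 tested genes.

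Counts were scaled with TMM factors (1.11, 1.18, 0.859 and 0.895 in the order above) and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with genotype as the only term, 2 residual degrees of freedom and a biological coefficient of variation of 0.249. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The design named the edgeR 4 default of the quasi-likelihood estimate, and the bias-adjusted estimate of edgeR 4 (legacy=FALSE) was used, although the function's own default in the installed version is the older estimate, which gave 2315 genes higher and 2434 lower. Levels are TMM-normalised CPM. Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with the preset inter-gene correlation of 0.01 and a variance trend, over lists with at least 5 tested members, adjusted over 45 lists. Within a list, members were also adjusted over the list alone. Camera with an estimated correlation, fry and ranks were run beside it. With an estimated correlation, camera's test rests on only the 2 residual degrees of freedom, so it can call few lists in this design.

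The tests, thresholds, gene lists and the rule for naming genes were chosen before the data were examined. The rule named Nr1d1 and 9 anchors, the 10 genes per direction with the largest log2 fold among named genes past the threshold with a mean of at least 5 CPM and no overlap between the genotypes, and up to 4 members of each described list that passed, lowest p first. Some genes that the rule would name are not reported here. Some listed members also stand in other lists, and bulk tissue lists describe transcript levels and not cells. Removal of the GC and length trends was chosen after the data were seen. It fitted natural splines with 5 degrees of freedom of each library's counts on GC content and transcript length and passed the fit to edgeR as offsets, for 14640 genes with both properties. The fit without Rn45s and small structured RNAs was also chosen after the data were seen.

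The tests were tested on simulated data for this comparison of 2 against 2, drawn for 14801 genes from the real means with 200 genes changed. Genes were drawn independently of one another with a shared dispersion, and far fewer were changed than were called in the real data. The rates below therefore need not hold for the real data, where members of some lists vary together. EdgeR called 19% of genes changed 2-fold, 97% of those changed 4-fold and 0.0274% of unchanged genes, and 3.33% of its calls were unchanged genes. With a GC trend of 0.05 log2 per % added, 0.678% of unchanged genes were called with the trend left in and 0.0479% with it removed. A simulated 2-fold rise of the glycolysis list was called with the preset correlation and not with an estimated one.

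Alternatives were other scalings (DESeq2 size factors, upper quartile, library size only), no filter or a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom, the older and the robust quasi-likelihood estimates, an adjusted p of 0.1, a minimum absolute log2 fold of 1, and leaving out each library in turn. The tests above did not pair samples by replicate number, since the labels do not say what the numbers share, and a fit with the replicate number as a block was run as an alternative. The mitochondrially encoded list had no member in the files and was not tested. Splits of 2 against 2 are too few for a test of other groupings. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.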

Results

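RNA sequencing measured transcript levels in mammary tumours of female FVB mice that carry the polyoma virus middle T antigen (PyMT), an oncogene that drives mammary carcinoma when it is expressed in the gland. All 4 tumour samples were taken at 14 weeks of age, and 2 of them were labelled Nr1d1+/+ and 2 were labelled Nr1d1-/-. Nr1d1 encodes REV-ERBα, a nuclear receptor of the circadian clock that represses transcription, and the study is known to concern NR1D1, the cGAS-STING pathway of cytosolic DNA sensing and antitumour immunity. The comparison asks which transcripts differ between the tumours of both genotypes. The total counts were 19116279 and 17768820 in Nr1d1+/+ replicates 1 and 2 and 15905404 and 18017279 in Nr1d1-/- replicates 1 and 2. The labels do not say that the replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. Levels below are mean ± SD of normalised counts (CPM, n = 2 per genotype). Each log2 fold is the libraries labelled Nr1d1-/- over those labelled Nr1d1+/+ with its standard error (SE).

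Transcripts of Nr1d1 itself were not clearly lower in the libraries labelled Nr1d1-/-. Nr1d1 lies on chromosome 11 from 98767932 to 98775333 on the minus strand (GRCm38), and its level was 20.2 and 10.3 CPM in Nr1d1+/+ replicates 1 and 2 and 10.6 and 12.8 CPM in Nr1d1-/- replicates 1 and 2. The log2 fold was -0.37 (SE 0.35, edgeR adjusted p = 0.436), and it was 0.15 without Nr1d1+/+ replicate 1. The labels do not say which exons the null allele lacks, and counts over exons that remain transcribed would not check the genotype, so the directions given here rest on the sample labels alone. Thra, which encodes a thyroid hormone receptor, spans 98740638 to 98769006 on the opposite strand and overlaps the end of Nr1d1. Whether counting used the strand is not given in the sources used here, so both genes' values are uncertain. Thra went from 32.2 ± 5.45 to 20.5 ± 1.35 CPM, log2 fold -0.65, SE 0.23, and its edgeR adjusted p of 0.0557 became 0.0107 with GC and length trends removed and 0.00774 with library size as the only scaling.

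The paralog Nr1d2, which encodes REV-ERBβ, fell from 37.2 ± 6.08 to 11.7 ± 1.71 CPM (log2 fold -1.67, SE 0.25, edgeR adjusted p = 0.0029). Its log2 fold was -1.15 with GC and length trends removed (edgeR adjusted p = 0.0143). Core clock and clock output genes were lower as a list in the libraries labelled Nr1d1-/-: 8 of the 23 tested members fell, 1 rose and 14 did not pass (1 rose and 9 fell adjusted over the list alone). Clock transcripts follow the hour of day, and whether the tumours were collected at the same hour could not be checked here. An effect of the hour is therefore not separated from one of genotype. Bhlhe40, a clock repressor, fell from 61.8 ± 3.99 to 27 ± 5.14 CPM (log2 fold -1.19, SE 0.21). Timeless fell from 31.8 ± 2.15 to 12.3 ± 4.39 CPM (log2 fold -1.36, SE 0.28). The member that rose was Rorb, a retinoid-related orphan receptor, from 13.5 ± 3.45 to 79.2 ± 38.1 CPM (log2 fold 2.55, SE 0.35). Arntl, which encodes BMAL1 and is a classical target of REV-ERBα repression, had a log2 fold of 0.56 (SE 0.40, edgeR adjusted p = 0.307), which ran from 0.18 without Nr1d1+/+ replicate 1 to 0.997 without Nr1d1+/+ replicate 2. Dbp, a clock output gene, had 0.20 (SE 0.32, edgeR adjusted p = 0.658). The sign for Dbp turned to -0.44 with GC and length trends removed, to -0.17 with library size only and to -0.19 without Nr1d1+/+ replicate 2. The clock list passed limma's camera at an adjusted p of 0.0496 (adjusted p = 0.729 with an estimated correlation). It did not pass with the trends removed (0.148), over genes with a mean of at least 5 CPM (0.0544) or without Nr1d1+/+ replicate 1 (0.0932), Nr1d1-/- replicate 1 (0.073) or Nr1d1-/- replicate 2 (0.112), all as limma camera adjusted p, and limma's fry gave 0.0719. With the trends removed fry gave 0.0111, which passed. How many members were called lower depended on the library left out, with fewer in every such fit but the one without Nr1d1-/- replicate 2. The list's median log2 fold was -0.49. It was -0.53 without Nr1d1+/+ replicate 1, -0.51 without Nr1d1+/+ replicate 2, -0.55 without Nr1d1-/- replicate 1 and -0.50 without Nr1d1-/- replicate 2. Genes known to be repressed by REV-ERBα did not move together: 2 of 16 tested rose, 4 fell and 10 did not pass (2 rose and 4 fell adjusted over the list alone), with a limma camera adjusted p of 0.648. Without Nr1d1+/+ replicate 2, 2 rose and 2 fell. Among them Lpl, lipoprotein lipase, rose from 185 ± 76.9 to 996 ± 435 CPM and Cx3cr1 rose from 8.18 ± 1.68 to 23.9 ± 3.47 CPM, while Scd1, the stearoyl-CoA desaturase, fell from 882 ± 428 to 200.3 ± 38.6 CPM and Elovl5 fell from 46.5 ± 6.41 to 17.7 ± 2.15 CPM.

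**Figure D1:**
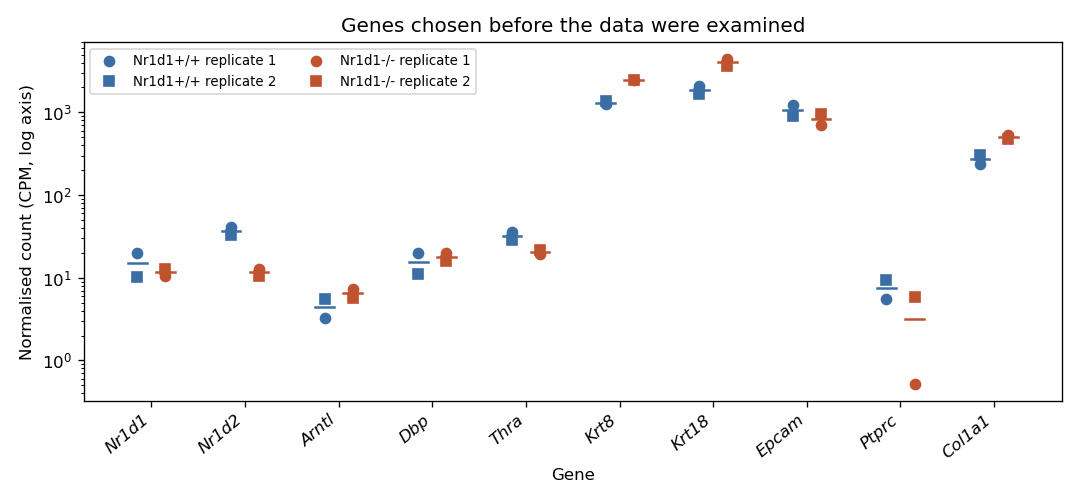
Normalised counts (CPM, log axis) of Nr1d1 and the other 9 genes chosen in advance in each of the 4 libraries, with points for libraries and bars for the mean of each genotype. Nr1d2 fell from 37.2 to 11.7 CPM, while the Nr1d1 values of both genotypes overlap.

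Across the tumours, 2446 of 14801 tested genes were higher and 2565 were lower in the libraries labelled Nr1d1-/- by edgeR, which is 33.9% of the tested genes. Higher genes were more often short and GC-rich, and lower genes more often long and GC-poor. The median log2 fold was 0.69 for transcripts under 1000 bases and -0.47 for those of at least 5000 bases, and it was -0.54 below 40% GC and 0.67 at or above 60% GC. The Spearman correlation of the log2 fold across genes was 0.314 with GC content and -0.321 with transcript length. Genes are not independent replicates, and the same correlations for the difference between both Nr1d1+/+ libraries were -0.14 and 0.18. For the difference between both Nr1d1-/- libraries they were 0.028 and -0.0917. With the GC and length trends removed from each library, 1701 genes were higher and 1586 lower, and 1408 of the higher and 1436 of the lower genes were called in both fits. With library size as the only scaling, 1281 were higher and 4410 lower, so that 22.5% of the calls were higher in place of 48.8%, with the median log2 fold of all genes at -0.38. Without Nr1d1+/+ replicate 2 the counts were 1212 and 1277. The genotypes' values did not overlap for 70.5% of the tested genes. The mean of that share over all ways to split the libraries into equal groups is 33.3%. Genes of a library vary together, so this comparison is no test against chance.

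**Figure D2:**
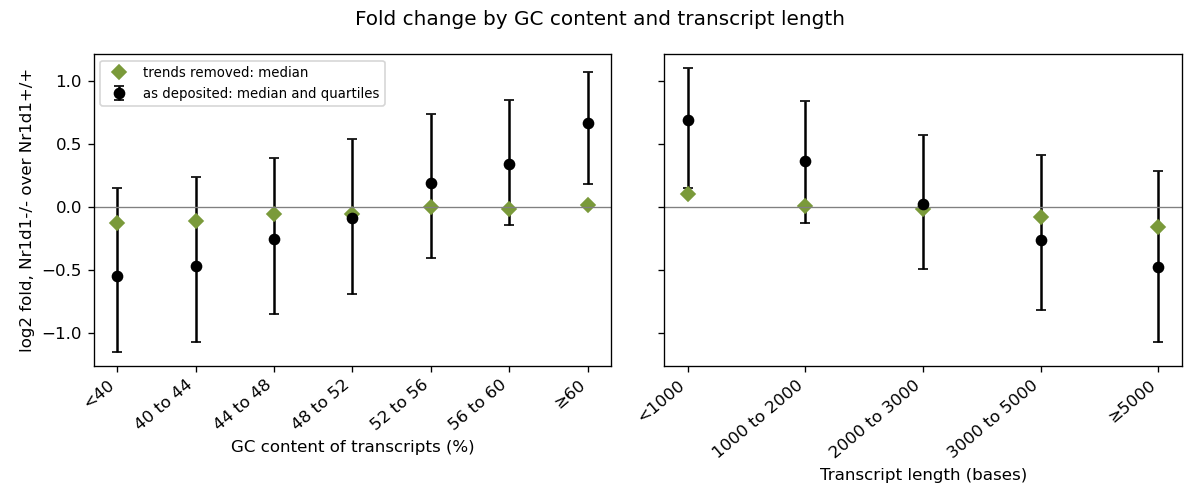
Median log2 fold (Nr1d1-/- over Nr1d1+/+, vertical axis) of genes binned by transcript GC content in % (left) and transcript length in bases (right); circles are medians with quartiles for the counts as deposited, and diamonds are medians with the trends removed. The median rises with GC content and falls with length.

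The RNA makeup of the libraries also differed with the genotype label. Rn45s, the precursor of ribosomal RNA, took 2.94% (95% interval 2.93 to 2.95) and 3.39% (95% interval 3.38 to 3.4) of the counts in Nr1d1+/+ replicates 1 and 2, against 4.36% (95% interval 4.35 to 4.37) and 7.64% (95% interval 7.63 to 7.65) in Nr1d1-/- replicates 1 and 2. Small structured RNAs, annotated as ribosomal, small nuclear or Cajal body RNAs, ribozymes or miscellaneous RNAs, took 0.00862% (95% interval 0.0082 to 0.00904) and 0.0275% (95% interval 0.0267 to 0.0283) against 0.109% (95% interval 0.107 to 0.11) and 0.182% (95% interval 0.18 to 0.184). The intervals are exact Clopper-Pearson intervals and cover counting error only. All 6 tested genes annotated as rRNA rose by edgeR, with a median log2 fold of 3.44. Of 186 tested lincRNA genes, 52 rose and 8 fell.

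Lists of cytosolic ribosomal protein, oxidative phosphorylation and glycolysis genes were higher in the libraries labelled Nr1d1-/-, though not every member passed. Of 56 tested cytosolic ribosomal protein genes, 42 rose and 14 did not pass (45 rose and 0 fell adjusted over the list alone), with a median log2 fold of 0.87. Rps19 rose from 491 ± 30.5 to 1291 ± 278 CPM (log2 fold 1.39, SE 0.21). Rps27 rose from 163 ± 2.12 to 392 ± 2.77 CPM (log2 fold 1.26, SE 0.17). Of 52 tested nuclear genes of oxidative phosphorylation, 34 rose, 1 fell and 17 did not pass (39 rose and 1 fell adjusted over the list alone), with a median log2 fold of 0.69. Ndufs8, a subunit of respiratory complex I, rose from 101 ± 5.64 to 274 ± 28 CPM (log2 fold 1.43, SE 0.18). The ATP synthase subunits Atp5d and Atp5e rose from 179.8 ± 5.39 to 457 ± 36.7 CPM and from 45.3 ± 6.01 to 126 ± 11.6 CPM. Of 23 tested glycolysis genes, 12 rose and 11 did not pass (12 rose and 1 fell adjusted over the list alone). Pdk4, a kinase that inhibits pyruvate dehydrogenase, rose from 14.7 ± 8.39 to 77.9 ± 16.4 CPM (log2 fold 2.40, SE 0.37). Ldhb rose from 99.7 ± 5.22 to 219 ± 30 CPM and Gapdh from 1046 ± 105 to 2143 ± 127 CPM. The limma camera adjusted p was 3.12e-13 for ribosomal proteins, 4.01e-10 for oxidative phosphorylation and 0.00539 for glycolysis. Each was 0.729 as an adjusted p with an estimated correlation. That correlation was estimated at 0.811, 0.328 and 0.070 in the same order, so the preset of 0.01 treats members as nearly independent. These correlations alone do not account for the 0.729. Clock genes and dendritic cell genes had the same 0.729 with estimates of -0.041 and -0.062, and the test has only the 2 residual degrees of freedom. Transcripts of the first 2 of these lists are short, with median lengths of 969.5 and 870.0 bases. With the GC and length trends removed, 11 ribosomal protein genes (median log2 fold 0.33), 11 oxidative phosphorylation genes (0.27) and 7 glycolysis genes (0.49) were still called higher. The limma camera adjusted p was then 0.000494, 0.00726 and 0.00832. Without Nr1d1+/+ replicate 2, 21 ribosomal protein, 19 oxidative phosphorylation and 4 glycolysis genes were called higher. Without Nr1d1-/- replicate 1, 21 ribosomal protein genes were, and without Nr1d1-/- replicate 2, 7 glycolysis genes were. With the trends removed, Rps27 (log2 fold 0.52, edgeR adjusted p = 0.0528) and Gapdh (0.49, edgeR adjusted p = 0.109) no longer passed.

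Replication-dependent histone transcripts were higher as a list, with 7 of 21 tested members called higher and 14 not passing (7 rose and 0 fell adjusted over the list alone). Hist1h2ae rose from 7.61 ± 0.0702 to 20.4 ± 0.26 CPM (log2 fold 1.42, SE 0.26) and Hist2h2aa1 from 136 ± 3.97 to 243 ± 12.2 CPM (log2 fold 0.84, SE 0.17). Near-identical histone genes can share reads, so single members are uncertain. For the histone list, limma's camera gave an adjusted p of 0.00539 (adjusted p = 0.729 with an estimated correlation). It became 0.261 with the GC and length trends removed, 0.0557 without Nr1d1+/+ replicate 1 and 0.112 without Nr1d1-/- replicate 2. With the trends removed, the log2 fold of Hist1h2ae was 0.76 (edgeR adjusted p = 0.0584) and that of Hist2h2aa1 turned to -0.32 (edgeR adjusted p = 0.221); with library size only, Hist2h2aa1 had 0.46 (edgeR adjusted p = 0.0546).

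Lists of red blood cell, endothelial and adipocyte genes were higher in the libraries labelled Nr1d1-/-. Of 10 tested red blood cell genes, 7 rose and 3 did not pass (7 rose and 0 fell adjusted over the list alone). The haemoglobin alpha gene Hba-a2 rose from 224 ± 33.4 to 990.1 ± 59.1 CPM (log2 fold 2.14, SE 0.20). The beta gene Hbb-bs rose from 46.5 ± 8.4 to 169.9 ± 5.82 CPM (log2 fold 1.87, SE 0.20). These genes have near-identical copies, so how counts split between copies is uncertain. Of 26 tested endothelial genes, 11 rose and 15 did not pass (14 rose and 0 fell adjusted over the list alone). Mmrn2 rose from 3.57 ± 0.636 to 20.6 ± 7.32 CPM (log2 fold 2.52, SE 0.36). Eng, the co-receptor endoglin, rose from 7.5 ± 1.24 to 23.1 ± 0.795 CPM (log2 fold 1.63, SE 0.26). Of 24 tested adipocyte genes, 8 rose, 1 fell and 15 did not pass (8 rose and 1 fell adjusted over the list alone). The fatty acid binding protein gene Fabp4 rose from 31.9 ± 10.8 to 91.8 ± 12.2 CPM and the glycerol channel gene Aqp7 from 21.4 ± 11.1 to 91.9 ± 25.2 CPM, while Acsl1, an acyl-CoA synthetase, fell from 56.3 ± 8.59 to 23.4 ± 4.51 CPM. The limma camera adjusted p was 0.000125 for red blood cells, 0.00958 for endothelium and 0.00958 for adipocytes. As an adjusted p with an estimated correlation it was 0.729, 0.729 and 0.768. Those correlations were 0.519, 0.134 and 0.559. Endothelial genes did not pass limma's camera without Nr1d1+/+ replicate 1 (adjusted p = 0.0557) or Nr1d1-/- replicate 2 (0.0599), and adipocyte genes did not without Nr1d1+/+ replicate 1 (0.0616) or Nr1d1-/- replicate 1 (0.142). The median log2 fold of the adipocyte genes was 1.11, and it was 0.38 with 5 rises without Nr1d1-/- replicate 1, the library with the high skeletal muscle counts described below. It was 0.52 with 5 rises without Nr1d1+/+ replicate 1 and 1.53 with 13 rises without Nr1d1-/- replicate 2. Fewer endothelial genes were called higher in every fit without 1 library but the one without Nr1d1-/- replicate 1. Their median log2 fold was 0.88. It was 0.72 without Nr1d1+/+ replicate 1, 1.03 without Nr1d1+/+ replicate 2, 0.99 without Nr1d1-/- replicate 1 and 0.78 without Nr1d1-/- replicate 2.

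Fibroblast and extracellular matrix genes had 11 rises and 2 falls among 36 tested, and 23 did not pass (11 rose and 2 fell adjusted over the list alone). Col1a1, the main collagen of connective tissue, rose from 272 ± 46.9 to 509 ± 38.5 CPM (log2 fold 0.91, SE 0.19, edgeR adjusted p = 0.00869), with 0.52 and 0.0538 under library size only. Mmp3 rose from 5.95 ± 0.791 to 21.5 ± 3.17 CPM and Acta2, smooth muscle actin, from 22.3 ± 1.8 to 92 ± 60.6 CPM, while Thbs1, thrombospondin, fell from 385 ± 174 to 57.5 ± 2.91 CPM. The log2 fold of Acta2 went from 2.04 to 1.14 without Nr1d1-/- replicate 2. This list missed the threshold (limma camera adjusted p = 0.146) and passed with the GC and length trends removed (0.0312), without Nr1d1+/+ replicate 2 (0.000469) and without Nr1d1-/- replicate 1 (0.00668). Its median log2 fold of 0.14 turned to -0.24 with library size only, to -0.04 without Nr1d1+/+ replicate 1 and to -0.04 without Nr1d1-/- replicate 2. In this list 7 rose and 4 fell without Nr1d1+/+ replicate 1, and 14 rose and 1 fell without Nr1d1+/+ replicate 2. Long non-coding and nuclear-retained RNAs had 7 rises and 1 fall among 15 tested, and 7 did not pass (7 rose and 2 fell adjusted over the list alone). H19, an imprinted long RNA of foetal tissues, rose from 16.3 ± 0.609 to 89.5 ± 14.8 CPM (log2 fold 2.46, SE 0.21) and Snhg11 from 50 ± 26.9 to 219 ± 70.3 CPM. For the long RNAs limma's camera gave an adjusted p of 0.149, 0.0226 with the trends removed and 0.0271 without Nr1d1+/+ replicate 2, and the median log2 fold of 0.17 turned to -0.21 with library size only. With an estimated correlation the adjusted p was 0.823 for fibroblast genes and 0.729 for long RNAs.

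**Figure D3:**
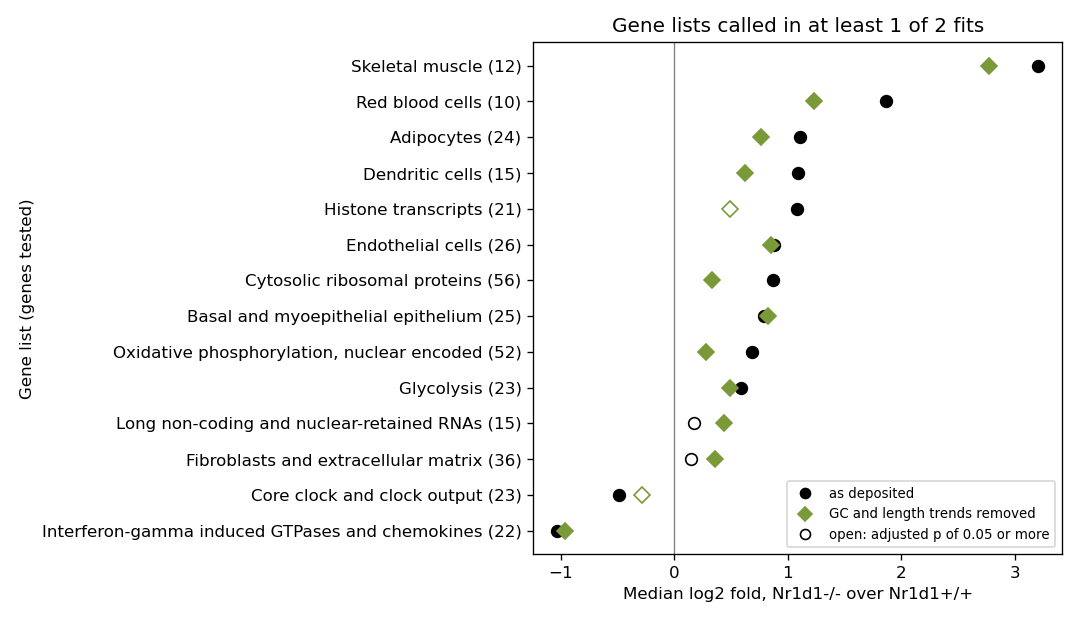
Median log2 fold (Nr1d1-/- over Nr1d1+/+) of the 14 gene lists called in at least 1 of the 2 fits, with the number of tested genes in brackets; circles show the counts as deposited and diamonds the fit with GC and length trends removed, and open symbols had an adjusted p of 0.05 or more. Skeletal muscle has the highest median and interferon-gamma induced genes the lowest.

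Epithelial genes went both ways. The luminal keratin genes Krt8 and Krt18 rose from 1311 ± 59.6 to 2477 ± 26 CPM (log2 fold 0.92, SE 0.20) and from 1855 ± 284 to 4029 ± 605 CPM (log2 fold 1.12, SE 0.24), with edgeR adjusted p-values of 0.00945 and 0.00882. With GC and length trends removed the log2 folds were 0.51 and 0.60 (edgeR adjusted p = 0.104 and 0.106), and with library size only they were 0.54 and 0.74 (0.0329 and 0.0124). Epcam, an adhesion molecule of epithelial cells, had 1064 ± 222 to 828 ± 179 CPM (log2 fold -0.36, SE 0.23, edgeR adjusted p = 0.251), and -0.73 and 0.0226 with library size only. Without Nr1d1+/+ replicate 1 the log2 fold of Epcam was -0.17, and without Nr1d1-/- replicate 1 it was -0.16. Of 25 tested basal and myoepithelial genes, 9 rose, 2 fell and 14 did not pass (9 rose and 2 fell adjusted over the list alone). Krt14, a basal keratin, rose from 62.1 ± 4.56 to 206 ± 5.36 CPM (log2 fold 1.73, SE 0.17) and Vim, vimentin, from 224 ± 46.1 to 492 ± 98.2 CPM, while Itga6, an integrin subunit, fell from 135 ± 20.1 to 35.7 ± 8.11 CPM (log2 fold -1.92, SE 0.22). The basal list had a limma camera adjusted p of 0.0345 (adjusted p = 0.729 with an estimated correlation) and of 0.132 without Nr1d1-/- replicate 2. Its median log2 fold went from 0.79 to 0.43 without Nr1d1-/- replicate 2. Milk protein and luminal alveolar genes had 4 falls and 1 rise among 25 tested, 20 did not pass (1 rose and 4 fell adjusted over the list alone), and the limma camera adjusted p was 0.278. The median log2 fold of this list was -0.35. It was -0.36 without Nr1d1+/+ replicate 1, -0.08 without Nr1d1+/+ replicate 2, -0.26 without Nr1d1-/- replicate 1 and -0.33 without Nr1d1-/- replicate 2. The falls were led by Xdh, xanthine dehydrogenase (176 ± 9.96 to 52.6 ± 1.87 CPM, log2 fold -1.74, SE 0.18), the receptor gene Kit (log2 fold -2.15, SE 0.23) and the whey protein gene Wap (324 ± 89.7 to 96.6 ± 11.4 CPM, log2 fold -1.75, SE 0.23).

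Genes induced by interferon-gamma were lower as a list: 12 of the 22 tested fell, 3 rose and 7 did not pass (3 rose and 12 fell adjusted over the list alone). Irgm1, an immunity-related GTPase, fell from 67 ± 2.59 to 25.6 ± 0.604 CPM (log2 fold -1.39, SE 0.19). Irgm2 fell from 22 ± 4.9 to 6.94 ± 1.42 CPM (log2 fold -1.66, SE 0.30) and the guanylate-binding protein gene Gbp7 from 23.3 ± 11.5 to 4.16 ± 2.36 CPM (log2 fold -2.46, SE 0.47). Cd274, which encodes the checkpoint ligand PD-L1, went the other way, from 50.5 ± 25.2 to 194 ± 34.2 CPM (log2 fold 1.94, SE 0.32). For this list limma's camera gave an adjusted p of 0.0361 (adjusted p = 0.729 with an estimated correlation). It was 0.0663 without Nr1d1+/+ replicate 2, 0.0785 without Nr1d1-/- replicate 1 and 0.0544 over genes with a mean of at least 5 CPM, and 7 members were called lower with the GC and length trends removed. Without Nr1d1+/+ replicate 2, 1 rose and 5 fell. Interferon-stimulated genes, which type I interferon induces, did not move together: 7 of 42 rose, 12 fell and 23 did not pass (8 rose and 14 fell adjusted over the list alone), with a limma camera adjusted p of 0.648. That balance held without Nr1d1+/+ replicate 1 or Nr1d1-/- replicate 2 and turned in 3 other fits: 4 rose and 2 fell with the GC and length trends removed, 11 rose and 5 fell without Nr1d1-/- replicate 1, and 5 rose and 0 fell without Nr1d1+/+ replicate 2. The members with the lowest p were rises, Ifi27l2a from 8.79 ± 1.39 to 38.3 ± 9.33 CPM, Ifitm3 from 84.6 ± 9.5 to 199 ± 22.4 CPM and Irf7 from 134 ± 1.17 to 292 ± 96.8 CPM. The log2 fold of Irf7 went from 1.12 to 0.74 without Nr1d1-/- replicate 2. Of 23 tested genes of cGAS-STING and cytosolic nucleic acid sensing, 6 rose, 6 fell and 11 did not pass (6 rose and 6 fell adjusted over the list alone), with a limma camera adjusted p of 0.814. The transcription factor gene Irf3 rose from 42.9 ± 2.16 to 97.8 ± 14.8 CPM (log2 fold 1.19, SE 0.19). Rnaseh2a, a ribonuclease H2 subunit, rose from 38.5 ± 0.0224 to 97.4 ± 28.5 CPM (log2 fold 1.34, SE 0.23), while Nfkb1 fell from 48.3 ± 3.84 to 22.5 ± 2.01 CPM (log2 fold -1.10, SE 0.21). The median log2 fold of this list was -0.04, its mean was 0.05, and the camera direction was higher. The median turned to 0.02 without Nr1d1+/+ replicate 1 and to 0.08 without Nr1d1+/+ replicate 2, where 4 rose and 2 fell. It was 0.02 with upper quartile scaling, 0.08 with the trends removed and -0.41 with library size only, so no direction is given for this list.

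Few lists of immune cell markers moved as a group. Ptprc, the pan-leukocyte gene CD45, was at 5.54 and 9.38 CPM in Nr1d1+/+ replicates 1 and 2 and at 0.513 and 5.83 CPM in Nr1d1-/- replicates 1 and 2 (log2 fold -1.18, SE 0.69, edgeR adjusted p = 0.218). Without Nr1d1-/- replicate 2 its log2 fold was -3.84 with an edgeR adjusted p of 0.00266, while it was -0.35 without Nr1d1-/- replicate 1 (0.585) and -0.76 without Nr1d1+/+ replicate 2 (0.54). Dendritic cell genes were higher as a list, with 3 of 15 tested called higher and 12 not passing (3 rose and 0 fell adjusted over the list alone). Xcr1, a chemokine receptor of cross-presenting dendritic cells, rose from 2.66 ± 0.449 to 14.9 ± 2.41 CPM (log2 fold 2.47, SE 0.34). Siglech, a plasmacytoid dendritic cell gene, rose from 5.6 ± 2.71 to 46.4 ± 32.3 CPM (log2 fold 3.04, SE 0.52). The limma camera adjusted p of the dendritic list was 0.0196 (adjusted p = 0.729 with an estimated correlation) and 0.0537 without Nr1d1-/- replicate 2. Its median log2 fold of 1.09 was 0.58 without Nr1d1+/+ replicate 2 and 0.56 without Nr1d1-/- replicate 2, and 6 members rose without Nr1d1-/- replicate 1. Of 19 tested T cell genes, 5 rose, 1 fell and 13 did not pass (5 rose and 1 fell adjusted over the list alone). Bcl11b rose from 7.65 ± 1.95 to 30.5 ± 1.83 CPM and Il7r from 5.92 ± 1.67 to 24.4 ± 4.15 CPM. The limma camera adjusted p was 0.149, or 0.033 over genes with a mean of at least 5 CPM (adjusted p = 0.729 with an estimated correlation). How many T cell genes were called higher depended on the library left out, with fewer in every such fit but the one without Nr1d1-/- replicate 2. Their median log2 fold was 0.71. It was 0.82 without Nr1d1+/+ replicate 1, 0.53 without Nr1d1+/+ replicate 2, 0.51 without Nr1d1-/- replicate 1 and 0.95 without Nr1d1-/- replicate 2. Cytotoxic effector genes split, with 2 of 8 tested called higher, 2 lower and 4 not passing (3 rose and 2 fell adjusted over the list alone), and the limma camera adjusted p was 0.648. There 1 rose and 1 fell without Nr1d1+/+ replicate 1, and 1 rose and 1 fell without Nr1d1+/+ replicate 2. Among them Lag3 rose from 4.9 ± 0.16 to 14.5 ± 3.6 CPM (log2 fold 1.55, edgeR adjusted p = 0.00803, and 1.03 and 0.0513 with the GC and length trends removed), while Tnf fell from 2.4 ± 0.686 to 0.192 ± 0.168 CPM (log2 fold -3.53, edgeR adjusted p = 0.0107, and -3.24 and 0.0815 without Nr1d1+/+ replicate 1). Tnf lay near the floor of 3 counts in the libraries labelled Nr1d1-/-, so the size of its fall is uncertain. Of 29 tested macrophage and monocyte genes, 7 rose, 3 fell and 19 did not pass (7 rose and 3 fell adjusted over the list alone). C1qa, a complement component made by macrophages, rose from 28.9 ± 1.12 to 111 ± 28.7 CPM (log2 fold 1.94, SE 0.22) and Apoe from 765 ± 229 to 2509 ± 313 CPM. The macrophage list had a limma camera adjusted p of 0.0999, and of 0.0205 over genes with a mean of at least 5 CPM (adjusted p = 0.823 with an estimated correlation). Its median log2 fold of 0.56 was 0.26 without Nr1d1+/+ replicate 1 and 0.17 without Nr1d1-/- replicate 2. That median was 0.85 without Nr1d1+/+ replicate 2 and 0.69 without Nr1d1-/- replicate 1.

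Skeletal muscle genes as a group were far higher in Nr1d1-/- replicate 1 than in the other 3 libraries. They took 0.0874% (95% interval 0.086 to 0.0889) of its counts, against 0.00376% (95% interval 0.00349 to 0.00406) in Nr1d1-/- replicate 2, 0.00355% (95% interval 0.00328 to 0.00382) in Nr1d1+/+ replicate 1 and 0.00354% (95% interval 0.00327 to 0.00383) in Nr1d1+/+ replicate 2. Acta1, skeletal muscle actin, was at 148 CPM in Nr1d1-/- replicate 1, 0.683 in Nr1d1-/- replicate 2 and 0.426 and 0.575 in Nr1d1+/+ replicates 1 and 2. Of 12 tested muscle genes, 7 were called higher and 5 did not pass (8 rose and 0 fell adjusted over the list alone), with a limma camera adjusted p of 0.0157 (adjusted p = 0.768 with an estimated correlation). Without Nr1d1-/- replicate 1, 2 members were called, the median log2 fold went from 3.21 to 0.47 and the limma camera adjusted p was 0.302. Without Nr1d1-/- replicate 2, 11 members were called. Over genes with a mean of at least 5 CPM it was 0.0594. The largest rises among the named genes belonged to this list: Acta1 at 7.19 (SE 1.87), the troponin gene Tnni2 at 6.54 (SE 1.55), the myosin light chain gene Mylpf at 6.22 (SE 1.54) and the calcium pump gene Atp2a1 at 5.34 (SE 1.41). Without Nr1d1-/- replicate 1 these were 0.44, 2.15, 2.09 and 1.16, with edgeR adjusted p-values of 0.719, 0.0436, 0.0533 and 0.291. Mylpf had a count of 1 in Nr1d1+/+ replicate 2, under the floor of 3 counts, so the size of its rise is uncertain. The muscle intermediate filament gene Des had a log2 fold of 4.16 (SE 0.92), and of 1.79 without Nr1d1-/- replicate 1. Limma-voom and edgeR's robust estimate called none of these 5 genes, and adjusted p-values for Acta1 were 0.456 and 0.288 there.

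**Figure D4:**
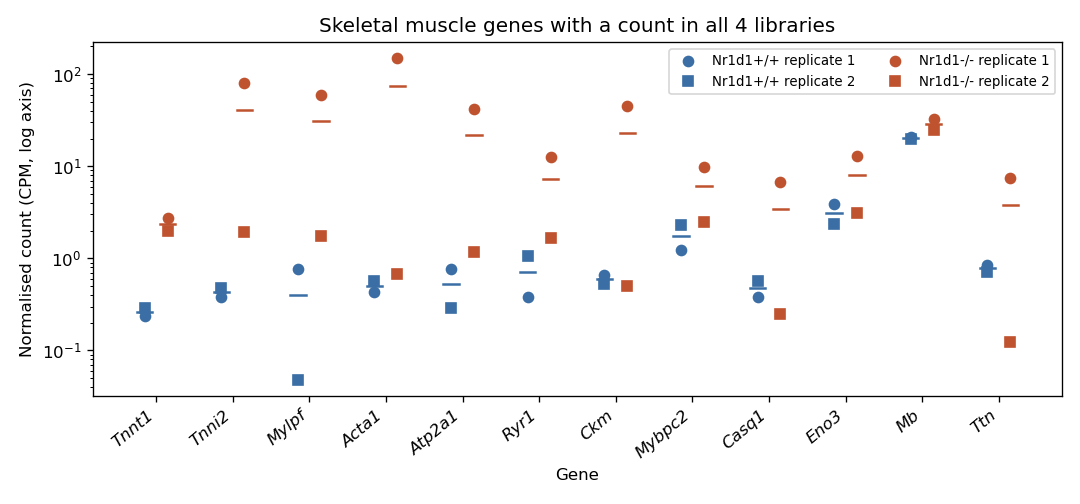
Normalised counts (CPM, log axis) of those of the 12 tested skeletal muscle genes that had a count in all 4 libraries. Points are libraries and bars are the mean of each genotype. Acta1 reached 148 CPM in Nr1d1-/- replicate 1 and stayed under 1 CPM in the other 3.

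The naming rule covered named genes past the threshold with a mean of at least 5 CPM and no overlap between the genotypes. Outside muscle, the largest rises among these included Npy, the neuropeptide Y gene, Nr2e1, an orphan nuclear receptor of neural progenitors, and Apoc1, an apolipoprotein. Zfp457, a zinc finger gene, and Dcpp1, a secreted salivary protein gene, also belonged to them. Apoc1 rose from 7.11 ± 0.579 to 114 ± 57.8 CPM (edgeR adjusted p = 0.00109), Nr2e1 from 1.05 ± 0.0762 to 17.5 ± 7.24 CPM (log2 fold 4.05, SE 0.45) and Zfp457 from 1.29 ± 0.886 to 19 ± 8.99 CPM (log2 fold 3.87, SE 0.53). Npy went from 9.76 ± 9.54 to 185 ± 186 CPM (log2 fold 4.24, SE 0.89), with 53.6 and 316 CPM in Nr1d1-/- replicates 1 and 2 and a log2 fold of 2.45 without Nr1d1-/- replicate 2. Dcpp1, one of several near-identical genes, had a log2 fold of 5.27 (SE 1.21), and 2.68 without Nr1d1-/- replicate 1. Its count in Nr1d1+/+ replicate 2 was 0, so no fold is given without Nr1d1+/+ replicate 1. Dcpp1 was not called by DESeq2, limma-voom or edgeR's robust estimate (adjusted p = 0.154, 0.15 and 0.213), and Npy was not called by the robust estimate (0.204).

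The largest falls among genes that the naming rule covered included several that were near 1 CPM in both libraries labelled Nr1d1-/-. Cyp24a1, the vitamin D hydroxylase, fell from 19 ± 2.05 to 1.71 ± 0.0363 CPM (log2 fold -3.47, SE 0.34, edgeR adjusted p = 0.00132). Slfn9, a Schlafen family gene, fell from 14.6 ± 4.3 to 0.86 ± 0.802 CPM (log2 fold -4.01, SE 0.54). Tmtc3 fell from 42.4 ± 10.1 to 4.39 ± 0.815 CPM and Mob1a, a Hippo pathway adaptor, from 11.3 ± 1.71 to 1.29 ± 0.247 CPM. Fem1c, a ubiquitin ligase substrate receptor, fell from 12.2 ± 7.68 to 1.39 ± 0.407 CPM and Spred2, an inhibitor of Ras signalling, from 14.2 ± 0.524 to 1.82 ± 1.16 CPM. These 4 genes had log2 folds of -3.26, -3.13, -3.11 and -3.00 (SE 0.30, 0.41, 0.58 and 0.44). The X-linked genes Xlr4b and Xlr4c, which are near-identical and so uncertain one by one, had log2 folds of -5.65 (SE 0.91) and -5.06 (SE 0.88). Xlr4b was at 60.6 CPM in Nr1d1+/+ replicate 1 and 11 in Nr1d1+/+ replicate 2, and without Nr1d1+/+ replicate 1 the log2 folds were -3.99 for Xlr4b and -3.54 for Xlr4c. Gbp4, an interferon-induced GTPase gene, had a log2 fold of -4.12 (SE 1.17) that rested on Nr1d1+/+ replicate 2 at 27.8 CPM, against 2.51 in Nr1d1+/+ replicate 1, and without it the log2 fold was -1.55 (edgeR adjusted p = 0.259). Without Nr1d1-/- replicate 2 it was -6.63, which rests on a count of 2 in Nr1d1-/- replicate 1, under the floor of 3 counts. The edgeR adjusted p of Gbp4 was 0.0549 with the trends removed (log2 fold -3.59), and DESeq2 gave 0.0625 (log2 fold -4.21). Dppa1 had a log2 fold of -3.33 (SE 0.76), and of -1.96 without Nr1d1+/+ replicate 1. Limma-voom did not call Xlr4b, Xlr4c, Gbp4 or Dppa1 (adjusted p = 0.0631, 0.0594, 0.207 and 0.0659), and edgeR's robust estimate did not call Xlr4b, Gbp4 or Dppa1 (0.0504, 0.211 and 0.0629).

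In all, 10 of the 45 tested lists were higher and 2 were lower by limma's camera, and 33 did not pass. Of the 12 that passed, 10 also passed in the same direction with GC and length trends removed, though 0 lists passed there with an estimated correlation. In the fit without trend removal, limma's camera with an estimated correlation called 0 lists, and 0 had an unadjusted p under 0.05. That test has only the 2 residual degrees of freedom and missed the simulated 2-fold rise of the glycolysis list. Its 0 calls therefore decide little for or against a list. Limma's fry, which asks whether a list's genes move one way on balance, also called 0 lists, and 17 had an unadjusted p under 0.05. Among the lists that did not pass were class I antigen presentation, with 4 of 23 tested called higher, 2 lower and 17 not passing (4 rose and 2 fell adjusted over the list alone), and fatty acid and triglyceride synthesis, with 4 of 25 called higher, 7 lower and 14 not passing (4 rose and 7 fell adjusted over the list alone). Their limma camera adjusted p was 0.747 and 0.269. The class I list had a median log2 fold of 0.06 and a mean of -0.06, and its camera direction was higher. The class I median turned to -0.09 without Nr1d1+/+ replicate 2, where 2 rose and 1 fell, and to -0.13 without Nr1d1-/- replicate 2. It was -0.32 with library size only and -0.12 with the trends removed. How many fatty acid genes were called changed with the library left out. Their median log2 fold was -0.33. It was -0.28 without Nr1d1+/+ replicate 1, -0.39 without Nr1d1+/+ replicate 2, -0.34 without Nr1d1-/- replicate 1 and -0.30 without Nr1d1-/- replicate 2. Elovl6, a fatty acid elongase gene, rose from 48.2 ± 13.2 to 218 ± 79.2 CPM, and Scd2, a second desaturase gene, fell from 252 ± 14.2 to 126 ± 10.1 CPM.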

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

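With all other choices kept, library size as the only scaling gave 1281 genes higher and 4410 lower by edgeR, a minimum absolute log2 fold of 1 gave 1501 higher, and the GC and length trends removed, chosen after the data were seen, gave 1586 lower. Leaving out 1 library gave 1212 to 2463 genes higher and 1277 to 2548 lower; the library left alone in its genotype is then assumed to vary like the others. Lists called higher by limma numbered 0 with an estimated correlation, where 0 had an unadjusted p under 0.05, 0 with fry, where 17 did, and 6 to 16 without 1 library. Lists called lower numbered 0 with an estimated correlation, with fry and with a mean of at least 5 CPM, 1 with the trends removed, 1 with the replicate block and 0 to 1 without 1 library. The replicate block gave 2622 genes higher and 2704 lower, a limma camera adjusted p of 0.0597 for the clock list and an edgeR adjusted p of 0.0492 for Ptprc (log2 fold -1.53). Deviations of replicates with the same number had a correlation of 0.0260 across genotypes. The log2 fold of Nr1d1 ran from -0.79 to 0.15 without 1 library. That of Dbp was -0.17 with library size only, -0.44 with trends removed, -0.40 with trends removed and the replicate block, and -0.19 to 0.67 without 1 library. That of Hist2h2aa1 was -0.32 with trends removed and -0.32 with the block added, and that of Thy1, a gene chosen after its values were seen, -0.091 with library size only, -0.13 with trends removed and -0.15 with the block added. Some lists that did not pass changed direction, with these limma adjusted p-values. Without 1 library they ran over 0.207 to 0.935 for REV-ERBα-repressed genes, 0.243 to 0.935 for interferon-stimulated genes, 0.463 to 0.967 for class I presentation, 0.741 to 0.978 for NK cell genes, 0.430 to 0.936 for mast cell genes, 0.263 to 0.981 for chemokines, 0.206 to 0.936 for mitosis, 0.692 to 0.936 for skin genes and 0.359 to 0.929 for genes next to Nr1d1. With trends removed and then with the block added they were 0.464 and 0.415 for class I presentation, 0.842 and 0.831 for luminal hormone-sensing genes and 0.861 and 0.893 for mitosis. Ranks gave 0.983 for mast cell genes and fry 0.830 for skin genes. Over the alternatives, 3024 gene values kept direction and call, 189 lost the call, 6 gained it and 10 changed direction; the cause was not tested. Pseudocounts and filters meant for normalised values were not run because the files hold counts, and the cytotoxic, NK cell, B cell, mast cell and skin lists gave no value with a mean of at least 5 CPM.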

Other observations

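Apart from the planned tests of gene lists and single genes, the percent of calls kept with GC and length trends removed and the count of neural transcripts, the tests below were chosen only after the result was seen. The percent of calls kept and the count of neural transcripts were set before their own results were seen, but after the data had been seen. Several genes outside the naming rule, chosen after their values were seen, were higher in both libraries labelled Nr1d1-/-. They include genes of neurons and of other organs: Dcc, a netrin receptor, rose from 41.3 ± 3.52 to 259.8 ± 2.09 CPM (log2 fold 2.65, SE 0.18). The vesicle gene Rab3c rose from 153 ± 24 to 893 ± 62.7 CPM (log2 fold 2.54, SE 0.20), Cplx2, complexin, from 288 ± 66.7 to 1436 ± 209 CPM (log2 fold 2.32, SE 0.23) and Nkx2-1, a transcription factor of lung and thyroid, from 318 ± 43.5 to 1442 ± 128 CPM (log2 fold 2.18, SE 0.20). The kallikrein gene Klk14 rose from 2066 ± 201 to 10397 ± 3381 CPM. Among the Schwann cell and nerve genes, 5 of 14 tested rose, 2 fell and 7 did not pass (5 rose and 2 fell adjusted over the list alone), and the limma camera adjusted p was 0.44. S100b rose from 4.07 ± 0.605 to 22.3 ± 5.12 CPM, while Cdh19 fell from 17.4 ± 0.728 to 4.23 ± 0.545 CPM. Within 10 Mb on either side of Nr1d1, 93 of 277 tested genes were called against 4867 of 14362 elsewhere (odds ratio 0.986, 0.758 to 1.28, Fisher p = 0.949), and with trends removed 76 of 277 against 3164 of 14362 (1.34, 1.01 to 1.76, Fisher p = 0.0341). The Fisher test treats genes as if they were independent, so its intervals and p-values do not measure the spread between samples.

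Many genes differed between the genotypes in both directions. With the GC and length trends removed, 56.8% of the called genes were still called with the same sign, and 22.2% of the tested genes were called. The trends as fitted here may explain part of the difference and did not account for all calls. The fit took GC and length from a single annotated transcript per gene. What such a fit misses was not tested, so the trends as the whole cause are not ruled out. The share of counts from small structured RNAs was at least 3.95 times higher in each library labelled Nr1d1-/- than in either labelled Nr1d1+/+, and a difference in RNA integrity or handling that goes with the genotype is a candidate explanation that cannot be separated from it here. Loss of repression by REV-ERBα was not shown by its known targets (limma camera adjusted p = 0.648, range over alternatives 0.207 to 0.935), whose mean log2 fold was -0.24. The 95% interval of that mean over members, which treats genes as if they were independent, was -0.93 to 0.46, and the list's median of -0.19 turned to 0.05 with trends removed and to 0.32 without Nr1d1+/+ replicate 2.

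The skeletal muscle list was called higher, mainly through 1 of the 2 libraries labelled Nr1d1-/-. All 12 tested muscle genes were highest in Nr1d1-/- replicate 1, each at over 1.3 times the next library, and 3 of the 12 (Tnnt1, Tnni2 and Mylpf) were over 2 times higher in each library labelled Nr1d1-/- than in either labelled Nr1d1+/+. Skeletal muscle tissue in that sample is a candidate explanation, and an effect shared by both libraries is not what most of these genes show.

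Some genes known from neural and other tissues, such as Rab3c, Cplx2, Dcc and Nkx2-1, were higher in both libraries labelled Nr1d1-/-. They were picked after their values were seen and do not stand for such genes as a set. Neural tissue in the samples would bring other abundant neural transcripts, and 3 of 16 listed ones, Map2, Camk2a and Thy1, were over 10 CPM in both of these libraries. The same 3 were also over 10 CPM in both libraries labelled Nr1d1+/+. By edgeR 1 of the 16 was called higher, Camk2a (log2 fold 1.98, SE 0.26), and 2 lower, Map2 (-1.38, SE 0.21) and Rbfox3 (-1.77, SE 0.50). The adjusted p of Rbfox3 was 0.198 without Nr1d1+/+ replicate 1, 0.0563 without Nr1d1+/+ replicate 2 and 0.053 without Nr1d1-/- replicate 1, with log2 folds of -1.45, -2.08 and -1.68. Expression of these genes in the tumour cells may be the source, and this was not tested.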
